A study of Mus musculus with 18 samples.

How the data were processed

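Gene expression was measured in the cerebellum of 18 mice of strain C57BL/6 with Affymetrix mouse arrays, 1 array per mouse, from total RNA that per the labels had an RNA integrity number above 5.0. The labels name 3 lines of homozygous mice, MPI 118Q knock-in, CtmKO and MPI 11Q knock-in, each beside its own wild-type littermates, with 3 arrays in each of the 6 groups. An age of 6 weeks is stated for the 118Q and CtmKO mice, and the age of the 11Q mice is not used here. The replicate numbers are not described as pairs, and the labels do not say more on how independent the replicates were than that they are separate samples, so each array was taken as 1 independent animal.

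The deposited values are log2 expression values per probe set, summarised and normalised by the authors with RMA according to the submitters' processing notes, which give no version. The log base was checked on the values: the highest of 12.2 would stand for an intensity of 191530 as a natural logarithm, above the 65535 a scanner with 16 bits can record. The labels do not give the zero point of the scale. Values reach down to -0.26, so the size of changes in dim genes depends on the background step used. The file held 45101 probe sets, of which 64 are array controls. The gene tests used the 34945 probe sets with exactly 1 gene symbol, and not the 10092 others, with several symbols or none in the probe table. For each gene the probe set with the highest mean over all 18 arrays was kept, which gave 18193 genes, 9010 of them with more than 1 probe set. No filter on dim genes was applied. A RefSeq gene table of assembly GRCm38.p6 was used for names, gene lengths and the order of genes along chromosomes only.

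Expression was compared with limma 3.58.1 in R 4.3.3: lmFit with 1 mean per group over all 18 arrays and eBayes with a constant prior, which left 12 residual and 5.98 prior degrees of freedom per gene. Two-sided moderated tests were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. The contrasts were mutant minus wild-type littermates in each line, the differences between these contrasts for each pair of lines, and an F test over the 3 wild-type groups. Every probe set of Cacna1a and Cacnb4 was also tested by itself. Gene lists were tested with limma camera at a preset inter-gene correlation of 0.01, adjusted over the 35 lists within a contrast, beside camera with an estimated correlation and fry. Array measures were compared by exact permutation tests, two-sided, which cannot go below 0.10 with 3 against 3 arrays. Agreement between lines was measured as the correlation of log2 changes across genes. The number of arrays limits the precision of every value.

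The comparisons, thresholds, lists, the rule for named genes and most alternatives were fixed before the data were examined. In each line the rule names the 12 largest rises and the 12 largest falls among called genes whose 3 mutant arrays all lie on 1 side of the 3 wild-type arrays, or, where fewer than 5 genes were called, the 5 smallest p values. It also names the 5 smallest p values of each difference between lines, up to 4 members of each list by smallest p, and always Cacna1a and Cacnb4. Predicted loci and the sex-linked probe sets used as array checks were left out of the named genes and kept in the counts. Genes named outside the rule are said to be chosen after their values were seen.

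The lists covered voltage-gated calcium channel subunits, genes linked to other Cav2.1 mutant mice, Purkinje cells, granule cells, cerebellar interneurons, Bergmann glia and astrocytes, reactive astrocytes, microglia, activated microglia, Toll-like receptors and cytokines, interferon response, oligodendrocytes and myelin, oligodendrocyte precursors, endothelial cells and pericytes, choroid plexus, hindbrain outside the cerebellum, meninges and fibroblasts, red blood cells, lysosome, autophagy, heat shock and chaperones, unfolded protein response, p53 and cell death, immediate early genes, neuropeptides and activity-regulated secretion, potassium and sodium channels, calcium signalling, synaptic vesicles and release, glutamate receptors, GABA receptors, oxidative phosphorylation, cholesterol synthesis, circadian clock, glucocorticoid response, and cell division with granule precursors. Of 688 list entries, 615 were measured with a probe set of their own. List members outside these 615 were not analysed here.

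The alternatives were every probe set tested by itself, the mean of a gene's probe sets, no dim genes (the dimmer 50% left out), eBayes with trend and robust settings, array weights, a renewed quantile normalisation, an RNA quality covariate (the 3' minus 5' log2 difference of the Gapdh and beta-actin control probe sets), a sex-linked covariate, the replicate number as a block, the arrays of the comparison alone, a fold change of at least 1.5 as well, and leaving out each array in turn. Chosen after seeing the data were a choroid plexus covariate, the omission of Ctm wild-type arrays 2 and 3 or of Ctm knockout arrays 2 and 3, and the 6 wild types of both knock-in lines as 1 control group.

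The procedure was tested on simulated data with 18193 genes and 3 arrays per group. Changed genes were drawn from those above the median level. The noise was normal, independent between genes and had the same SD in every group, which the real Ctm groups did not. Of the genes given a log2 change of 1, it recovered 65 of 66 in the simulated 118Q comparison, 59 of 66 in the Ctm comparison and 63 of 66 in the 11Q comparison, with 5, 10 and 7 false calls. Camera also called 2 lists that had not been shifted in the simulated Ctm comparison, and 0 in the others. At a log2 change of 0.5 it recovered 26, 28 and 32 of 68. These rates hold for the simulated data only. Other splits of the real arrays within a line called up to 13 lists in 118Q, 9 in Ctm and 8 in 11Q. The simulated counts therefore do not show how often lists are falsely called on the real arrays.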

Results

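Cerebellar expression was profiled in 3 lines of mice with altered Cacna1a, the gene of the Cav2.1 calcium channel, to study spinocerebellar ataxia type 6. Each of the 6 groups held 3 arrays: 118Q knock-in, Ctm knockout and 11Q knock-in mice, each with wild-type littermates of its own line. Array medians lay between 2.38 and 2.55 on the log2 scale, and correlations between pairs of arrays between 0.973 and 0.995. Values below are log2 changes, mutant minus wild type, with the standard error (SE) of limma's model.

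The mean 3' minus 5' difference of the Gapdh and beta-actin control probe sets, a measure of RNA quality, was 0.45 ± 0.030 (SD, n = 3) in 118Q knock-in arrays and 0.55 ± 0.060 (SD, n = 3) in their wild types, with no overlap. A two-sided exact permutation test gave p = 0.10, the smallest this design allows (adjusted p = 0.525 over the array measures). In the Ctm line it was 0.618 in knockouts and 0.614 in wild types (exact p = 0.90), and in the 11Q line 0.674 and 0.640 (exact p = 0.70). Transcripts of the choroid plexus, the epithelium that makes cerebrospinal fluid, varied widely between arrays of every line: Ttr, its most abundant transcript, ran from 5.30 to 12.1. Xist stayed between 1.28 and 2.18 on all 18 arrays, below every array median. The Y-linked gene Eif2s3y stayed between 4.57 and 6.37, above every array median. No array thus read as female by these genes, and the sex-linked covariate holds no contrast of males and females. Ctm wild-type arrays 2 and 3 were the lowest of all 18 in Eif2s3y, at 5.07 and 4.57, and in the Y-linked gene Uty, at 2.83 and 2.84.

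Cacna1a itself did not pass the test in any line. Where its probe sets lie relative to the altered part of the gene is not known, so an unchanged signal does not check the alteration. On its brightest probe set (1450510_a_at) its level was 5.64 ± 0.13 (SD, n = 3) in 118Q knock-in and 5.93 ± 0.38 in wild type. It was 6.04 ± 0.17 in Ctm knockout and 6.10 ± 0.071 in wild type, and 6.24 ± 0.058 in 11Q knock-in and 6.32 ± 0.097 in wild type. The changes were -0.29 (SE 0.15, adjusted p = 0.341), -0.061 (SE 0.15, adjusted p = 0.910) and -0.086 (SE 0.15, adjusted p = 0.933). The Ctm value was 0.023 without Ctm knockout array 3, and with the mean of all Cacna1a probe sets the Ctm and 11Q values were 0.12 and 0.16, all short of the threshold. Another Cacna1a probe set (1430408_at) was 0.61 higher in the Ctm knockout (SE 0.20, adjusted p = 0.185 over all probe sets), at 5.31 ± 0.11 against 4.70 ± 0.50. Cacnb4, which encodes an auxiliary beta subunit of the channel, was 0.53 higher in the Ctm knockout on its brightest probe set (1436912_at, SE 0.12, adjusted p = 0.0520), just short of the threshold. All 3 knockouts lay above all 3 wild types. A dimmer Cacnb4 probe set (1428928_at) rose by 0.49 in the Ctm knockout (SE 0.10, adjusted p = 0.0323 over all probe sets). Another (1452089_at) was at 0.38 in limma's test (SE 0.25, adjusted p = 0.640 over all probe sets). On 1428928_at the Ctm wild types averaged 7.65 and the knockouts 8.14, with 7.87 and 7.95 in 118Q and 11Q wild types. On the brightest probe set the Ctm wild types, at 8.91, were not below the 8.71 and 8.89 of these other wild types. In the 118Q and 11Q lines the brightest Cacnb4 probe set differed by -0.31 (SE 0.12, adjusted p = 0.211) and -0.15 (SE 0.12, adjusted p = 0.884).

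**Figure D1:**
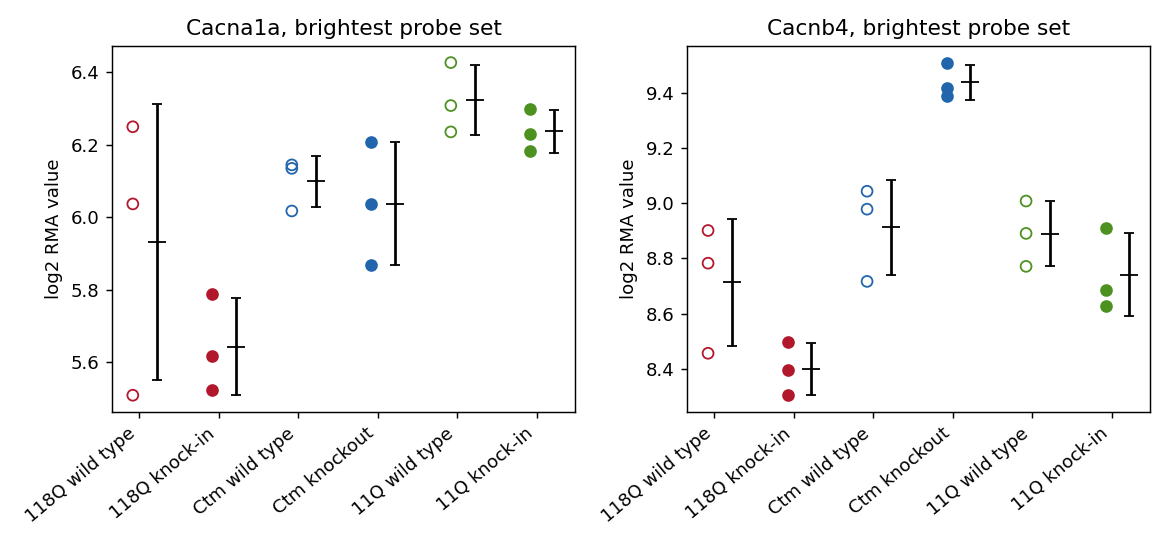
Log2 RMA value of the brightest probe sets of Cacna1a and Cacnb4 in the 6 groups, with 1 point per array (open, wild type; filled, mutant) and a bar for the mean and SD of 3 arrays. Cacnb4 averages 9.44 in the Ctm knockout and 8.91 in its wild types, while the Cacna1a groups overlap in the Ctm line.

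In the 118Q knock-in cerebellum, 4 of 22 microglia markers rose, while 6 of 20 Purkinje cell markers, 2 of 16 endothelial and pericyte markers and 5 of 23 calcium signalling genes fell. Calb1 is counted among the falls of both the Purkinje cell and the calcium signalling list. These 4 lists passed camera, but no list did with an estimated correlation (smallest adjusted p = 0.0705). Trem2, a receptor of microglia, rose by 0.89 (SE 0.11), its signalling adaptor Tyrobp by 1.03 (SE 0.17) and the macrophage lysosomal glycoprotein gene Cd68 by 1.03 (SE 0.23). Among Purkinje cell genes, the glutamate transporter gene Slc1a6 was at -1.11 (SE 0.18), Dner, which encodes a Notch ligand, at -1.10 (SE 0.21) and the kinase gene Stk17b at -0.96 (SE 0.14), all of them falls past the threshold with n = 3 per group. Of 18193 genes, 280 changed by limma at an adjusted p below 0.05: 147 rose and 133 fell. In 279 of the 280 the groups did not overlap, and over all genes they did not in 18.1%, against 10% by chance.

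Other large rises in the 118Q knock-in were those of H2-Bl, a gene of the major histocompatibility class I family, with 1.26 (SE 0.25), the chemokine gene Cxcl14 with 0.96 (SE 0.23), and Cenpb, which encodes a centromere protein, with 0.95 (SE 0.14). Folh1, which encodes the glutamate carboxypeptidase that cleaves N-acetylaspartylglutamate, rose by 0.88 (SE 0.16) and the leukocyte surface gene Cd52 by 0.87 (SE 0.16). Bcl2l11, a pro-apoptotic member of the Bcl-2 family, rose by 0.84, Olfml1 by 0.84, the glycine methyltransferase gene Gnmt by 0.80 and S100a1, a calcium-binding protein gene, by 0.79, with SE from 0.14 to 0.21. The largest fall was that of Fgf14, whose product binds voltage-gated sodium channels, at -1.62 (SE 0.34). Another of its 4 probe sets was at -1.72 in 118Q and the remaining 2 at -0.15 and 0.029. Nell1 was at -1.42, the metabotropic glutamate receptor gene Grm7 at -1.35 and Shisa6, an auxiliary subunit gene of AMPA receptors, at -1.33. The neurturin receptor gene Gfra2 was at -1.30 and Strip2 at -1.23. Phxr4 was at -1.20, the alpha-tubulin gene Tuba8 at -1.19, the protein kinase A anchoring gene Akap2 at -1.16 and the fatty acyl-CoA reductase gene Far2 at -1.13. The SE of these 9 falls lay between 0.14 and 0.30. Adjusted p values of all these genes ran from 0.00130 for Tuba8 to 0.0475 for Bcl2l11. Phxr4 was also low in the Ctm wild types, at -1.15 relative to the mean of the 6 wild types of the knock-in lines.

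By gene list, 14 of 35 lists passed camera in the 118Q line, 3 higher and 11 lower. With an estimated correlation none passed, and the smallest adjusted p was 0.0705. With fry 10 of the 35 lists passed. Of 20 Purkinje cell markers, 0 rose, 6 fell and 14 did not pass, and 12 fell when adjusted over the list alone. Car8, a regulator of the inositol trisphosphate receptor, was at -0.65 (SE 0.13). The median of the list was -0.39 (camera adjusted p = 2.2e-13; adjusted p = 0.0705 with an estimated correlation). Of 22 microglia markers 4 rose, and 11 when adjusted over the list alone, among them Laptm5, a lysosomal membrane protein gene, with 0.54 (SE 0.13). Their median was 0.46 (camera adjusted p = 9.3e-09; adjusted p = 0.0705 with an estimated correlation). Of 14 interneuron markers 1 fell, and 8 when adjusted over the list alone. The vesicular GABA transporter gene Slc32a1 was at -0.81 (SE 0.20). Lgi2, the GABA-synthesis gene Gad1 and Kit, at -0.68, -0.74 and -0.55, passed only over the list alone. The list had a median of -0.40 (camera adjusted p = 9.1e-08; adjusted p = 0.0904 with an estimated correlation). Of 16 endothelial and pericyte markers 2 fell, and 7 when adjusted over the list alone. The vascular growth factor receptor gene Flt1 was at -0.90 (SE 0.15) and the drug efflux gene Abcb1a at -0.90 (SE 0.21). Its median change was -0.41 (camera adjusted p = 1.3e-10; adjusted p = 0.0707 with an estimated correlation). The RNA quality measure of the 118Q knock-in arrays lay below that of their wild types in the same comparison, with 0.41 to 0.47 against 0.50 to 0.61. Purkinje cell and endothelial lists fell less on knock-in array 1 than on arrays 2 and 3. The mean deviation of the interneuron list on knock-in array 1 was -0.059, within the range of its wild types (-0.11 to 0.031). On knock-in arrays 2 and 3 it was -0.71 and -0.47.

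**Figure D2:**
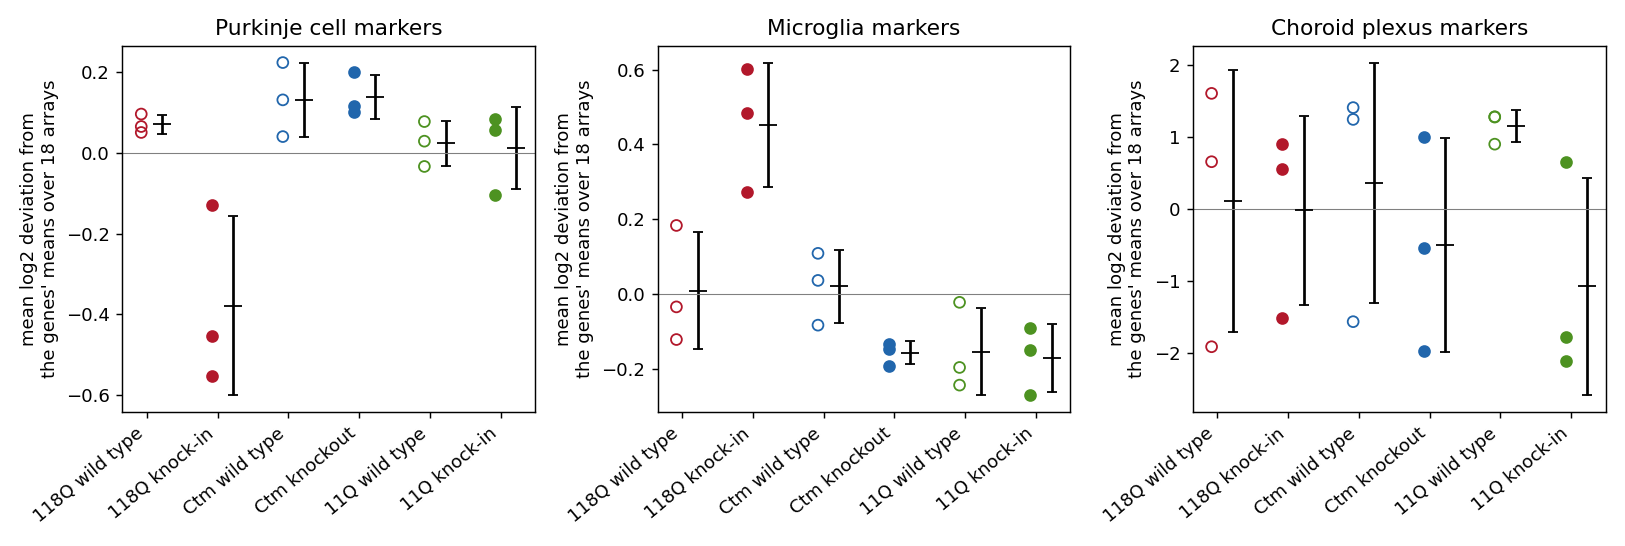
Mean log2 deviation of the Purkinje cell, microglia and choroid plexus lists from their genes' means over all 18 arrays, with 1 point per array (open, wild type; filled, mutant) and a bar for the mean and SD of 3 arrays per group. The 118Q knock-in arrays lie between -0.55 and -0.13 for Purkinje cell markers and between 0.27 and 0.60 for microglia markers, beyond every other array, and choroid plexus markers spread widely within most groups.

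Calcium-handling and channel genes were lower as lists by camera in the 118Q knock-in, though at an estimated correlation each of these lists had an adjusted p of 0.0705. Of 23 calcium signalling genes 5 fell, and 8 when adjusted over the list alone. The endoplasmic reticulum calcium pump genes Atp2a2 and Atp2a3 were at -0.69 (SE 0.11) and -0.84 (SE 0.20), the plasma membrane pump gene Atp2b2 at -0.42 (SE 0.10) and the calcium buffer gene Calb1 at -0.75 (SE 0.18). Over the list the median was -0.26 (camera adjusted p = 4.3e-09; adjusted p = 0.0705 with an estimated correlation). Of 19 potassium and sodium channel genes 4 fell, and 5 when adjusted over the list alone. Kcna6 was at -0.51 and the large-conductance potassium channel gene Kcnma1 at -0.85. The sodium channel genes Scn8a and Scn4b were at -0.50 and -0.73, with SE from 0.11 to 0.19. The members' median lay at -0.20 (camera adjusted p = 2.9e-05; adjusted p = 0.0705 with an estimated correlation). Of 17 calcium channel subunit genes 1 fell, Cacna2d2, at -0.74 (SE 0.13), and 3 when adjusted over the list alone. This adds Cacna1g at -0.53 and Cacnb2 at -0.39. The list had a median of -0.14 (camera adjusted p = 0.00201; adjusted p = 0.0705 with an estimated correlation). Cacna2d2 was also the 1 fall, over all genes and when adjusted over the list alone, among the 8 genes linked to other Cav2.1 mutant mice, where Ryr1 was at -0.55 and Nos1 at -0.26 without passing. Its median change was -0.18 (camera adjusted p = 0.00303; adjusted p = 0.0705 with an estimated correlation).

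Grm7 was the 1 of 19 glutamate receptor genes that fell in the 118Q knock-in. Adjusted over the list alone 5 fell and 1 rose, with Grik1 at -0.97, Grid1 at -0.46 and Gria1 at 0.39. The members' median lay at -0.12 (camera adjusted p = 0.00777; adjusted p = 0.160 with an estimated correlation). Without wild-type array 2 the list's camera adjusted p was 0.130, and without the dimmer 50% of genes 0.244. Of 26 synaptic vesicle genes 1 fell, Slc32a1, and 2 when adjusted over the list alone, the other being Pclo, a scaffold of the active zone, at -0.63. Snap25 and Nsf, at -0.32 and -0.26, did not pass. Over the list the median was -0.093 (camera adjusted p = 0.00309; adjusted p = 0.210 with an estimated correlation). Of 16 heat shock and chaperone genes 2 fell, Hspa4 at -0.57 (SE 0.11) and Hsp90aa1 at -0.54 (SE 0.13), and 4 when adjusted over the list alone. The latter adds Hspa8 at -0.43 and Hspd1 at -0.28. The members' median lay at -0.20 (camera adjusted p = 0.000322; adjusted p = 0.292 with an estimated correlation). None of 12 meningeal and fibroblast genes passed by limma over all genes or when adjusted over the list alone. All 12 were negative, with Lum at -0.49, Col1a2 at -0.29, Col1a1 at -0.26 and Slc6a13 at -0.20. Against the 6 wild types of both knock-in lines the list's mean was -0.11 and its call was lost (camera adjusted p = 0.0696). The list had a median of -0.23 (camera adjusted p = 0.000769; adjusted p = 0.133 with an estimated correlation). Of 15 glucocorticoid response genes all 15 were positive and 0 passed over all genes by limma, while 1 rose when adjusted over the list alone, the metallothionein gene Mt1 with 0.65. Sult1a1, Mt2 and Arrdc2 were at 0.94, 0.70 and 0.75. Its median change was 0.52 (camera adjusted p = 0.000522; adjusted p = 0.295 with an estimated correlation). Of 28 oxidative phosphorylation genes 0 passed over all genes and 8 rose when adjusted over the list alone. Among these 8 were Cox6c with 0.42, Ndufv2 with 0.27, Atp5o with 0.28 and Ndufa4 with 0.29. Over the list the median was 0.14 (camera adjusted p = 0.0498; adjusted p = 0.595 with an estimated correlation). The oxidative phosphorylation call was lost without wild-type array 1 (adjusted p = 0.389), knock-in array 1 (0.129) or knock-in array 3 (0.133). It was also lost with the mean of probe sets (0.248), without the dimmer 50% of genes (0.103), and with array weights (0.135), the RNA quality (0.148), sex-linked (0.0946) or choroid plexus covariate (0.0578). The replicate block (0.0792), the 6 arrays alone (0.141) and the 6 wild types as control (0.0665) ended it as well.

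The other 21 lists did not pass in the 118Q knock-in. Nearest to the threshold were activated microglia genes (median 0.16, camera adjusted p = 0.0549) and p53 and cell death genes (0.17, adjusted p = 0.0869). Medians were 0.027 for granule cell, 0.099 for Bergmann glia and astrocyte, -0.015 for reactive astrocyte, 0.017 for Toll-like receptor and cytokine, 0.046 for interferon response, 0.11 for oligodendrocyte and myelin, -0.15 for oligodendrocyte precursor, -0.12 for choroid plexus, -0.0018 for hindbrain and 0.14 for red blood cell genes. They were 0.030 for lysosomal, 0.049 for autophagy, 0.0075 for unfolded protein response, 0.21 for immediate early, -0.10 for neuropeptide, 0.021 for GABA receptor, 0.032 for cholesterol synthesis, 0.19 for circadian clock and 0.037 for cell division genes. Adjusted p values of these 19 lists lay between 0.114 and 0.967. In 9 of the 35 lists the median, the mean and the test differed in sign, none of them among the 14 that passed.

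The count of 280 genes in the 118Q line rested on single arrays and on the model. It was 68, 240 and 2 without wild-type arrays 1, 2 and 3, and 941, 7 and 3 without knock-in arrays 1, 2 and 3. Of 41 called genes named above, 18, 30, 2, 38, 6 and 2 kept their call in these 6 refits. It was 37 with the RNA quality covariate, 70 with replicate number as a block and 178 with every probe set tested by itself. It was 0 with the 6 arrays of the line alone, 424 with trend and robust settings, 567 without the dimmer 50% of genes, 1740 with array weights, 147 with a fold change of at least 1.5 as well, and 1660 against the 6 wild types of both knock-in lines.

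In the Ctm knockout, 169 genes changed, of which 152 were higher and 17 lower than in wild-type littermates by limma (n = 3 per group). Fut9, which encodes the fucosyltransferase that makes the Lewis x epitope, was 2.40 higher (SE 0.52), Sycp1, a gene of the synaptonemal complex, 2.15 (SE 0.36), and the amylase gene Amy1 1.71 (SE 0.23). Gadd45gip1, which encodes a protein of the mitochondrial ribosome, fell by 1.39 (SE 0.16), and Rasd2, a small GTPase gene, fell by 1.05 (SE 0.22). In the 152 higher genes the knockouts lay close to the other lines and the Ctm wild types below them. Relative to the 6 wild types of the knock-in lines, the median deviation was -0.096 in Ctm knockouts and -1.03 in Ctm wild types. It was -0.51, -1.18 and -1.32 in wild-type arrays 1, 2 and 3. Fut9 was at 7.46, 3.95 and 4.67 in these 3 wild types, and between 7.66 and 8.25 on the 15 arrays of the other groups.

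Most of the other rises named by the rule in the Ctm knockout were of zinc finger genes, Zfp995 with 2.24 (SE 0.46), Zfp946 with 2.09 (SE 0.45) and Zfp758 with 1.99 (SE 0.39). Zfp942 rose by 1.91 (SE 0.39), Zfp182 by 1.63 (SE 0.27) and Zfp711 by 1.57 (SE 0.32). Outside this family were Prpf39, which encodes a pre-mRNA splicing factor, with 1.67 (SE 0.34), Nbeal1 with 1.65 (SE 0.27) and Ftx, a noncoding RNA gene of the X-inactivation centre, with 1.59 (SE 0.26). Wild-type SD for these genes was between 0.53 and 1.59, and knockout SD between 0.020 and 0.25. For Fut9 the SD was 1.85 in wild types and 0.082 in knockouts. The SE of these rises rests on a spread shared by all 6 groups, so it understates the spread among the Ctm wild types. Ctm wild-type arrays 2 and 3 lay below all 15 arrays of the other groups in 147 and 151 of the 152 genes, and wild-type array 1 in 96. Against wild-type array 1 alone the median rise was 0.41, and against all 3 wild types 0.90.

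Falls in the Ctm knockout were smaller, and most had a like spread in both groups. An exception was Mri1, with an SD of 0.037 in knockouts and 0.38 in wild types. Mri1, which encodes an enzyme of methionine salvage, was at -0.79 (SE 0.18), the tRNA methyltransferase gene Trmt1 at -0.67 (SE 0.14), the deubiquitinase gene Usp38 at -0.63 (SE 0.15), and the small heat shock gene Hspb8 at -0.54 (SE 0.12). Trp53i13 was at -0.54, the proline synthesis gene Pycrl at -0.51 and Rom1, a photoreceptor disc gene, at -0.51. The glyoxylate reductase gene Grhpr was at -0.50, the dynein subunit gene Wdr34 at -0.49 and the cyclic nucleotide phosphodiesterase gene Pde8b at -0.48, with SE between 0.10 and 0.12. Adjusted p values of these 12 rises and 12 falls ran from 0.00128 for Gadd45gip1 to 0.0464 for Usp38. Gadd45gip1, Trmt1, Mri1, Usp38 and Rasd2 all lie within 200 measured genes of Cacna1a on chromosome 8. A second, dim probe set of Gadd45gip1 (mean 2.49) went the other way, at 0.69. Trmt1 was negative on all 3 of its probe sets, at -0.67, -0.29 and -0.20.

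By gene list, 4 of 35 passed camera in the Ctm knockout and none with an estimated correlation (smallest adjusted p = 0.265). Of 19 glutamate receptor genes 2 rose, both also when adjusted over the list alone. Gria2, an AMPA receptor subunit gene, rose by 1.18 (SE 0.19) and the kainate receptor gene Grik2 by 0.48 (SE 0.11). Gria4 and Grm3 were at 0.36 and 0.34. The members' median lay at 0.052 (camera adjusted p = 0.00266; adjusted p = 0.265 with an estimated correlation). Gria2 was at 8.05, 7.41 and 6.91 in the 3 Ctm wild types and between 8.28 and 8.76 on the other 15 arrays. Of 23 calcium signalling genes 0 passed over all genes by limma and 1 rose when adjusted over the list alone, the sodium-calcium exchanger gene Slc8a1 with 0.87 (SE 0.21). Plcb4, Camk4 and Ryr1 were at 0.30, 0.26 and 0.50. The list had a median of 0.050 (camera adjusted p = 0.0153; adjusted p = 0.697 with an estimated correlation). Of 30 lysosomal genes 0 passed over all genes by limma and 2 fell when adjusted over the list alone, Ctsa at -0.38 and the beta-galactosidase gene Glb1 at -0.44. The cathepsin genes Ctsz and Ctsh were at -0.39 and -0.49. Its median change was -0.18 (camera adjusted p = 0.000334; adjusted p = 0.265 with an estimated correlation). Of 12 meningeal and fibroblast genes 0 passed over all genes and 4 fell when adjusted over the list alone. These were Islr at -0.69, the collagen genes Col1a1 and Col1a2 at -0.37 and -0.34, and Fmod at -0.63. Over the list the median was -0.31 (camera adjusted p = 0.000584; adjusted p = 0.265 with an estimated correlation). The other 31 lists had adjusted p values from 0.0657 to 0.972. Purkinje cell markers had a median of -0.032 (adjusted p = 0.389) and microglia markers one of -0.25 (adjusted p = 0.141). Without knockout array 1, 2 lists passed, with an adjusted p of 0.0532 for glutamate receptors and 0.209 for calcium signalling, and without knockout array 3, 8 passed. With the sex-linked covariate these 2 lists had adjusted p = 0.0570 and 0.261, and calcium signalling had 0.0745 with the mean of probe sets.

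The count of 169 genes in the Ctm line was 447, 41 and 1 without wild-type arrays 1, 2 and 3 and 7, 24 and 33 without knockout arrays 1, 2 and 3. Of 26 called genes named above, 23, 7, 1, 2, 4 and 7 kept their call in these refits. It was 307 without the dimmer 50% of genes, 627 with array weights, 0 with the sex-linked covariate, 1 with the 6 arrays of the line alone, 4 without wild-type arrays 2 and 3, and 0 without knockout arrays 2 and 3. The sex-linked covariate, which holds no contrast of males and females here, is lowest on wild-type arrays 3 and 2 (1.91 and 2.19). It may therefore take up part of their distance from the other arrays, which was not tested.

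**Figure D3:**
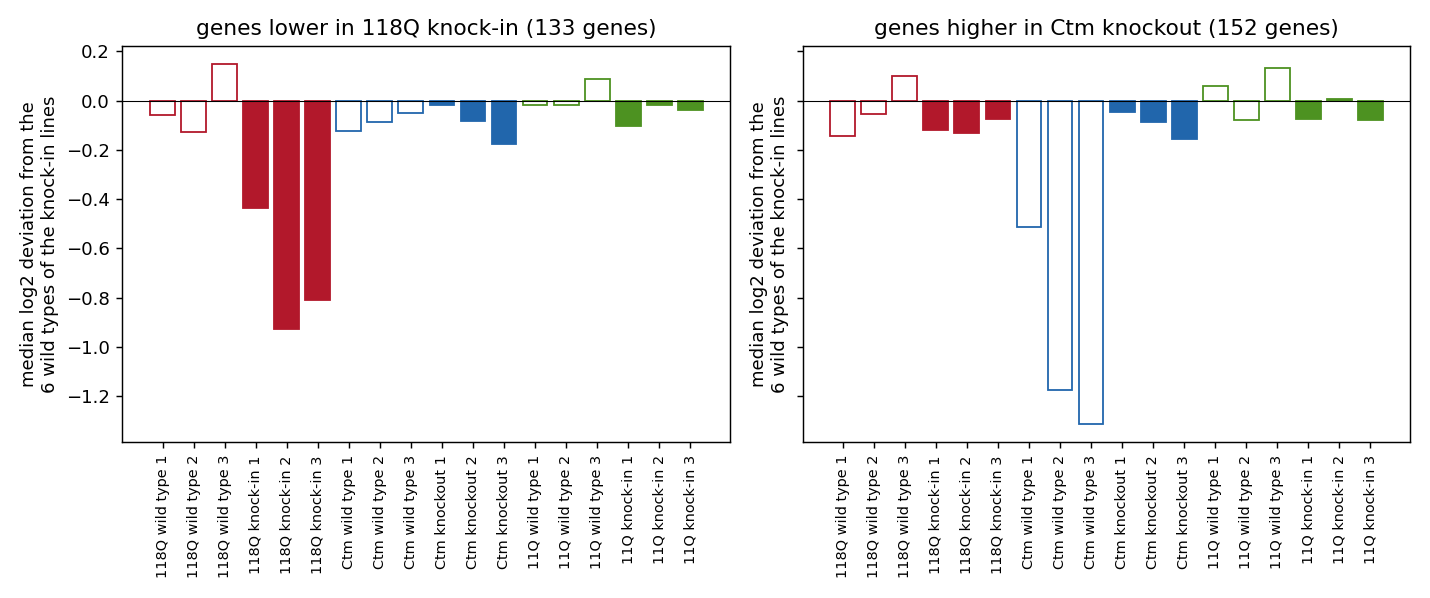
Median log2 deviation, on each of the 18 arrays, from the mean of the 6 wild types of both knock-in lines, for the 133 genes lower in the 118Q knock-in and the 152 genes higher in the Ctm knockout (open bars, wild type; filled bars, mutant). For the second set the Ctm wild types stand at -0.51, -1.18 and -1.32 and all other arrays between -0.16 and 0.13; for the first set the 118Q knock-in arrays stand between -0.93 and -0.44.

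In the 11Q knock-in, no gene passed by limma (998 at an unadjusted p below 0.05, smallest adjusted p = 0.111). The 5 smallest p values belonged to Comp, a cartilage matrix protein gene, at 2.50 (SE 0.41, adjusted p = 0.111), and Il33, which encodes a cytokine released on cell damage, at -1.08 (SE 0.18, adjusted p = 0.111). The others were Gadd45gip1 at -0.91 (SE 0.16, adjusted p = 0.130), the mitochondrial coenzyme A carrier gene Slc25a42 at 0.81 (SE 0.15, adjusted p = 0.156) and Lpcat2, a phospholipid acyltransferase gene, at -1.22 (SE 0.23, adjusted p = 0.159). Each was without overlap between its 3 knock-in and 3 wild-type arrays. Comp, Gadd45gip1, Slc25a42 and Lpcat2 lie within 200 measured genes of Cacna1a on chromosome 8. Comp was at 1.90 ± 0.23 (SD, n = 3) in 11Q wild types and 4.40 ± 0.075 in knock-ins, but also at 1.95, 4.06 and 4.19 in the 3 wild types of the 118Q line. Over all genes the groups did not overlap in 10.3%, against 10% by chance. The count of 0 became 1 without wild-type array 2.

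**Figure D4:**
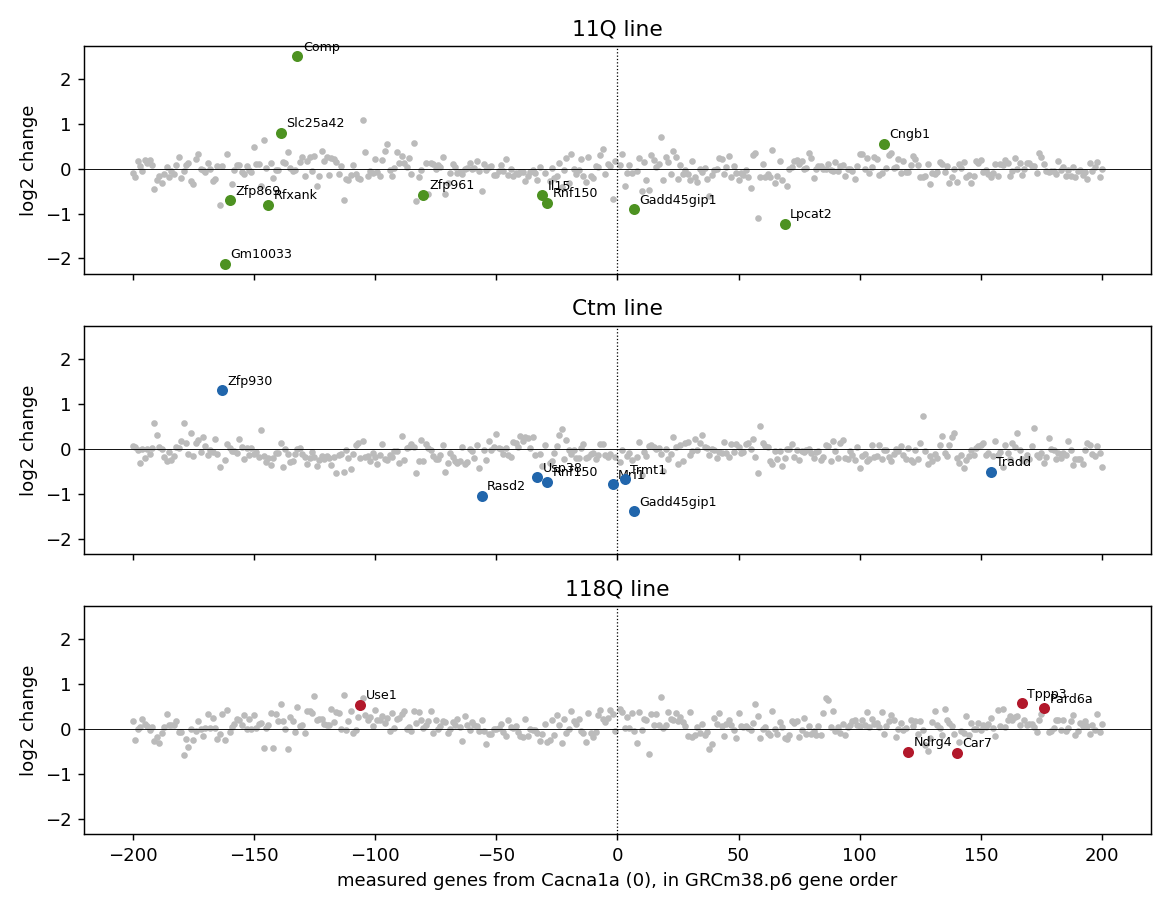
Log2 change, mutant minus wild type, of up to 200 measured genes on either side of Cacna1a on chromosome 8 in each line, placed by gene order in GRCm38.p6 with Cacna1a at 0. Coloured, named points have an unadjusted limma p below 0.001; 11 genes do in the 11Q line, among them Comp at 2.50 and Gadd45gip1 at -0.91.

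Of the 35 lists 6 passed camera in the 11Q knock-in, 2 higher and 4 lower, with none at an estimated correlation (smallest adjusted p = 0.728). Choroid plexus markers were lower, with a median of -2.11 over 11 genes, 0 called over all genes by limma and 2 lower when adjusted over the list alone. Col8a1 was at -1.60, the homeobox gene Otx2 at -0.70, the bicarbonate transporter gene Slc4a5 at -1.64 and Clic6 at -2.01 (camera adjusted p = 6.0e-09; adjusted p = 0.728 with an estimated correlation). Ttr was at 11.9, 11.9 and 11.9 in 11Q wild types and at 7.68, 5.30 and 11.8 in knock-ins. Interferon response genes were higher, with a median of 0.23 over 19 genes, 0 called over all genes by limma and 1 higher when adjusted over the list alone, Ifitm3 at 0.47. Usp18, Iigp1 and Ifit1 were at 0.87, 0.50 and 0.72 (camera adjusted p = 3.6e-05; adjusted p = 0.728 with an estimated correlation). The interferon list rested on knock-in array 1, where Ifit1 was at 3.67 against 1.69 and 1.73 on the other knock-in arrays. Without that array the mean change was -0.043 (camera adjusted p = 0.956).

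Granule cell markers (median 0.077, camera adjusted p = 0.0392), oligodendrocyte and myelin genes (-0.18, 0.00801), hindbrain markers (-0.19, 0.0209) and heat shock genes (-0.13, 0.0392) were the other lists past the threshold in the 11Q knock-in. They had adjusted p = 0.728, 0.786, 0.728 and 0.786 with an estimated correlation. None of their members passed by limma over all genes or when adjusted over the list alone. Named by smallest p were the granule cell genes Barhl1, Grin2c, Cbln1 and Slc17a7 at 0.32, 0.34, 0.21 and 0.41, and the oligodendrocyte genes Ermn, Aspa, Olig1 and Ndrg1 at -0.46, -0.40, -0.25 and -0.25. In the same way, the hindbrain genes Hoxb5, Hoxa3, Hoxb4 and Hoxc4 were at -1.07, -0.20, -0.25 and -0.42, and the chaperone genes Cryab, Hspa1a, Dnajb1 and Hsph1 at -0.68, -0.65, -0.32 and -0.32. Choroid plexus markers were at -1.79, -2.11 and 0.65 on knock-in arrays 1, 2 and 3, as mean log2 deviations from their genes' means. The 4 lists did not share this pattern. On the same arrays granule cell markers were at 0.021, 0.080 and 0.069 and oligodendrocyte genes at -0.57, -0.023 and -0.25. Hindbrain markers were at -0.10, -0.14 and -0.13 and heat shock genes at -0.17, -0.13 and -0.11. On wild-type array 3 the 4 lists were at -0.18, 0.067, 0.47 and 0.44, and choroid plexus markers at 0.90. All 4 lists lost their call without wild-type array 3 (camera adjusted p = 0.488, 0.140, 0.999 and 0.860 in the order above). The oligodendrocyte list also lost it without knock-in array 1 (0.621). The granule cell and hindbrain lists lost it without knock-in array 2 (0.0911 and 0.0911) or 3 (0.0955 and 0.0514), and the heat shock list without knock-in array 2 (0.148). With array weights all 4 calls were lost as well (0.161, 0.770, 0.230 and 0.294). With the RNA quality covariate the granule cell, hindbrain and heat shock calls were lost (0.101, 0.0609 and 0.111), and so they were with the choroid plexus covariate (0.226, 0.226 and 0.446). The granule cell call was lost with the mean of probe sets (0.111) and the 6 arrays alone (0.0727), and the hindbrain call with the sex-linked covariate (0.0774) and the 6 wild types as control (0.125). The heat shock call was lost without the dimmer 50% of genes (0.107), with renewed quantile normalisation (0.110), the sex-linked covariate (0.0774) and the 6 arrays alone (0.0724). The 29 lists that did not pass had adjusted p values from 0.142 to 0.990.

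Effects in the Ctm and 118Q lines differed in 533 genes by the test of the difference itself, 198 with a higher and 335 with a lower effect in Ctm. The 5 smallest p values were those of Cenpb, at -1.47 (SE 0.19; -0.52 in Ctm and 0.95 in 118Q), Eea1, an early endosome gene, at 1.04 (SE 0.16; 0.81 and -0.23), and the NADPH oxidase subunit gene Cyba at -0.98 (SE 0.15; -0.41 and 0.56). They were followed by the diacylglycerol kinase gene Dgkh at 1.51 (SE 0.24; 0.50 and -1.01) and Fgf14 at 2.95 (SE 0.47; 1.34 and -1.62). All 5 had adjusted p values from 0.00514 to 0.0145. Dgkh was also low in Ctm wild types (deviation -0.88). Fgf14 was at 6.66, 8.28 and 6.22 in these wild types and at 8.40, 8.46 and 8.31 in Ctm knockouts, so its difference of 2.95 rests partly on Ctm wild-type arrays 1 and 3. By list, 14 differed by camera, 10 higher and 4 lower in Ctm than in 118Q. None differed with an estimated correlation (smallest adjusted p = 0.0780), and 11 did with fry. Among the 14 were Purkinje cell markers with a median difference of 0.42 (camera adjusted p = 5.0e-09, and 0.0876 with an estimated correlation). Microglia markers were at -0.61 (camera adjusted p = 9.4e-07, and 0.117 with an estimated correlation). The count was 272 and 75 without 118Q wild-type arrays 1 and 3, and 1021, 156 and 89 without 118Q knock-in arrays 1, 2 and 3. In turn it was 347 and 24 without Ctm wild-type arrays 2 and 3, and 98, 145 and 172 without Ctm knockout arrays 1, 2 and 3. It was 6 without both Ctm wild-type arrays 2 and 3, 0 without both Ctm knockout arrays 2 and 3 and 67 with the RNA quality covariate. The count was 62 with the sex-linked covariate, 105 with the replicate block, 81 with the 12 arrays of both lines alone, 1061 without the dimmer 50% of genes and 1893 with array weights.

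No gene had an effect in the 118Q line that differed from that in the 11Q line by limma (1880 at an unadjusted p below 0.05). The smallest p values were those of Tuba8 at -1.13 (SE 0.19), the kinesin gene Kif1c at 0.91 (SE 0.16) and Trem2 at 0.85 (SE 0.15). Next were Fhit at 1.49 (SE 0.28) and Nckap1l, an actin regulator of blood cells, at 0.85 (SE 0.16), all with an adjusted p of 0.142. By list, 18 differed by camera, none with an estimated correlation (smallest adjusted p = 0.130) and 1 with fry. They included Purkinje cell markers at -0.34 (camera adjusted p = 9.1e-11) and microglia markers at 0.41 (camera adjusted p = 1.2e-06), with an adjusted p of 0.130 for both with an estimated correlation. The gene count was 1 and 2 without 118Q wild-type arrays 1 and 2, 91 without 118Q knock-in array 1, 75 with array weights and 4 with the choroid plexus covariate. Between the Ctm and 11Q lines, 0 genes differed by limma (1543 at an unadjusted p below 0.05). The RNA-binding gene Taf15 was at 1.37 (SE 0.22), the cadherin gene Cdh19 at 1.73 (SE 0.29), Amy1 at 1.86 (SE 0.33), Eea1 at 0.85 (SE 0.16) and Slf1 at 1.94 (SE 0.37). Adjusted p values of these 5 ran from 0.105 to 0.114. That count was 282 and 4 without Ctm wild-type arrays 1 and 2, 1 without Ctm knockout array 2, and 144 with array weights. The 3 lists that differed there were interferon response genes at -0.41, choroid plexus markers at 1.31 and meningeal genes at -0.47 (camera adjusted p = 0.00149, 0.0126 and 0.00172), with adjusted p = 0.777, 0.839 and 0.777 with an estimated correlation. With fry 0 lists differed between Ctm and 11Q.

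In both the 118Q and the Ctm line 3 genes were called, where 2.60 would be expected of independent lists. They are named here after their values were seen. Ovgp1 rose in both, by 0.68 and 0.95, the mitochondrial ribosomal protein gene Mrpl57 was at 0.43 and -0.47, and 4932438A13Rik at -0.51 and 0.52. Across all 18193 genes the log2 changes of 118Q and Ctm had a Pearson r of -0.149 and a Spearman rho of -0.174. Those of 118Q and 11Q had 0.125 and 0.104, and those of Ctm and 11Q had 0.057 and 0.023. These correlations run across genes, which are not independent replicates. Correlations at least as large in size arose in 24, 63 and 49 of 100 relabelings of the arrays within the lines, the real labels included.

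The wild-type littermates of the 3 lines differed among themselves in 1779 genes by limma's F test (4513 at an unadjusted p below 0.05). Any difference in array processing between the lines is part of this comparison, since the labels give no batches. Between 118Q and 11Q wild types 0 genes differed (753 at an unadjusted p below 0.05), and between Ctm and 11Q wild types 2250, with 987 higher and 1263 lower in Ctm. The F test gave 785 genes without Ctm wild-type array 2, 656 without array 3 and 26 without both. It gave 1 with the sex-linked covariate, which is lowest on these 2 arrays, 601 with the 9 wild types alone and 2916 with every probe set tested by itself.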

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

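The tests of array positions, of omitted Ctm arrays, of RNA quality in the Ctm line, of the make-up of the wild-type splits and of the fall shared with Ctm wild types were chosen after the results were seen; the splits of the arrays and the tests of RNA quality and gene length on the Purkinje cell list were set beforehand.

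The effects of the Ctm knockout and the 118Q knock-in differed in 533 genes by the test of the difference. The largest count from the other 99 of 100 splits within both lines was 51, so chance labels in both lines are argued against at 1 in 100. The splits relabel both lines, so they do not test whether the 2 effects are equal. A departure of 1 group, such as the Ctm wild types, would also raise the real count. Without Ctm wild-type array 3 the count was 24. Among the 5 genes with the smallest p, the Ctm effect minus the 118Q effect was -1.47 for Cenpb, 1.04 for Eea1, -0.98 for Cyba, 1.51 for Dgkh and 2.95 for Fgf14.

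Probe sets without a single gene symbol, which the gene comparisons do not use, also changed: 332 of 10092 in the 118Q knock-in, 63 higher and 269 lower, and 112 in the Ctm knockout, 108 higher and 4 lower. In the 11Q knock-in 0 passed by limma, with 466 at an unadjusted p below 0.05.

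Most calls in the Ctm line were genes higher in the knockout, 152 of 169. Loss of signal from the 5' end in degraded RNA is argued against: 11Q knock-in arrays 1 and 2, with a larger 3' minus 5' difference (0.716 and 0.707) than any Ctm wild type (up to 0.658), deviated in these genes by a median of -0.076 and 0.0075, against -1.18 and -1.32 in Ctm wild-type arrays 2 and 3. A departure of Ctm wild-type arrays 2 and 3 is a candidate explanation: in 146 of the 152 genes both lay below all 15 arrays of the other groups, 12 of which entered the choice of genes only through the variance. This position was tested after another test could not decide, in which 4 genes were called without these 2 wild-type arrays but 0 without Ctm knockout arrays 2 and 3. The knockouts deviated from the wild types of the knock-in lines by a median of -0.096, yet the effect of the Ctm genotype cannot be told apart from the departure, because the 1 other wild type of the line, array 1, was itself at -0.51 and below all 15 arrays in 96 of the genes, with a median rise of 0.41 against it alone.

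Genes lower in the 118Q knock-in included Purkinje cell markers, with a list median of -0.39. Low values shared with the Ctm wild types are argued against for the 133 falls as a set. Their median was -0.092 in the Ctm wild types and -0.72 in the knock-in, where they were chosen as falls. Still, 9 of them, among these Dgkh, Phxr4, Sema3e and Dmd, lay over 0.5 lower in all 3 Ctm wild types. A further 14, Fgf14 among them, did so in 1 or 2. A departure of the 118Q knock-in arrays themselves was not tested, and the falls had medians of -0.44, -0.93 and -0.81 on arrays 1, 2 and 3. RNA quality, only as far as the Gapdh and beta-actin control probe sets measure it, is argued against as the whole cause. With its covariate the Purkinje cell median was -0.32 (camera adjusted p = 4.4e-10). With an estimated correlation the camera adjusted p was 0.110, and 0.0705 without the covariate. A trend with gene length is argued against by a percentile of 0.01 among 10000 random lists matched on length and level, the smallest they can give. The covariate lowered the count of called genes from 280 to 37, and since its ranges in knock-ins and wild types do not overlap, it removes part of any genotype effect as well. A lower content of Purkinje cell transcripts with the 118Q genotype may therefore be put as a hypothesis. It is not one particular to these cells, since interneuron and endothelial lists had medians of -0.40 and -0.41. The interneuron list mean fell below its wild types on knock-in arrays 2 and 3 only. Whether cells were fewer or held less of these transcripts was not tested.

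For the counts of genes within a line, 3 against 3 arrays make 10 splits, too few for a share under 0.05: the 118Q line gave 280 genes and at most 2 in the other splits, the Ctm line 169 and at most 0, and the 11Q line 0 and at most 2. The same holds for the lists, with 14 in the 118Q line and at most 13 in the other splits, 4 and at most 9 in the Ctm line, and 6 and at most 8 in the 11Q line. For the differences of 118Q and of Ctm from 11Q, a real count of 0 is reached by all 100 of 100 splits whatever the data, so these splits, with up to 18 and 14 genes, decide nothing. Of 100 splits of the 9 wild types into 3 groups, 4 gave at least the 1779 genes of the real one, which is 1 of them, a share under 0.05. The 3 others as high gave up to 3277 and kept the 3 Ctm wild types together, so the splits do not single out the grouping by line. In all, 5 other splits kept these 3 together and gave 1553 to 3277 genes, and no split that parted them gave over 573. Splits with Ctm wild-type arrays 2 and 3 apart gave at most 22, and 30 other splits with these 2 together had a median of 0.5. The structure is thus one of Ctm wild types against the rest, in which line and processing batch are not separated. Chance is not excluded for the correlations of effects: r was -0.149 for 118Q and Ctm with 24 of 100 relabelings as large and another reaching 0.414 in size, 0.125 for 118Q and 11Q with 63 and 0.457, and 0.057 for Ctm and 11Q with 49 and 0.383.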

How the results depend on the processing

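The choroid plexus covariate, the omission of pairs of Ctm arrays and the 6 wild types of both knock-in lines as 1 control were chosen after seeing the data; the other settings were planned. Causes of the shifts were not tested unless stated: the cause was not tested for any count below.

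Genes called in the 118Q knock-in numbered 280, and 567 without the dimmer 50% of genes, 178 with every probe set by itself, 424 with trend and robust settings, 1740 with array weights, 37 with the RNA quality covariate, 70 with the replicate block, 0 with the arrays of the comparison alone, 147 with a fold of at least 1.5 as well and 1660 against 6 wild types. In the Ctm knockout, 169 became 307 without the dimmer genes, 627 with array weights, 0 with the sex-linked covariate, 1 with the arrays alone, 4 without wild-type arrays 2 and 3 and 0 without knockout arrays 2 and 3. In the 11Q knock-in, 0 became 1 with array weights, 1 with the block, 1 with the arrays alone and 1 against 6 wild types. Differences between 118Q and 11Q went from 0 to 75 with array weights and 4 with the choroid plexus covariate. Those between Ctm and 11Q went from 0 to 1 with the mean of probe sets, 144 with array weights, 1 with the arrays alone and 1 without Ctm wild-type arrays 2 and 3. Those between Ctm and 118Q went from 533 to 1061 without the dimmer genes, 1893 with array weights, 67 with the RNA quality covariate, 62 with the sex-linked covariate, 105 with the block, 81 with the arrays alone, 6 without the 2 Ctm wild types and 0 without the 2 knockouts. Genes differing among wild types went from 1779 to 2916 with every probe set, 1 with the sex-linked covariate, 601 with the arrays alone and 26 without the 2 Ctm wild types. With 1 or 2 arrays fewer, or 6, 9 or 12 arrays in place of 18, part of a loss comes from fewer residual degrees of freedom.

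Lists called in 118Q went from 14 to 0 with an estimated correlation and to 10 with fry. In Ctm they went from 4 to 0 with an estimated correlation, 2 with fry, 11 without the 2 wild types and 9 without the 2 knockouts. In 11Q they went from 6 to 0 with an estimated correlation, 0 with fry, 2 without the dimmer genes, 3 with the RNA quality covariate and 3 with the choroid plexus covariate, under which the choroid plexus list was not tested, as its own mean is the covariate. The correlation of 118Q and Ctm effects went from -0.149 to 0.0070 with the sex-linked covariate. That covariate holds no contrast of males and females and is lowest on Ctm wild-type arrays 3 and 2.

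Leaving out 1 array gave 2 to 941 genes in 118Q, 1 to 447 in Ctm, 0 to 1 in 11Q, 0 to 91 for 118Q against 11Q, 0 to 282 for Ctm against 11Q, 24 to 1021 for Ctm against 118Q and 656 to 1890 among wild types. It gave 14 to 16 lists in 118Q, 2 to 8 in Ctm and 4 to 7 in 11Q, and correlations of -0.190 to -0.101 for 118Q and Ctm, -0.0088 to 0.200 for 118Q and 11Q, and -0.0071 to 0.133 for Ctm and 11Q. The sign of Cacna1a reversed in Ctm with the mean of probe sets (0.12), without knockout array 3 (0.023, in a range of -0.15 to 0.023 over single arrays), without wild-type arrays 2 and 3 (0.020) and without knockout arrays 2 and 3 (0.11), and in 11Q with the mean of probe sets (0.16) and against 6 wild types (0.11). Hoxc4 reversed in 11Q without wild-type array 3 (0.029, from -0.66 to 0.029 over single arrays), Slc6a13 in 118Q against 6 wild types (0.072), and the interferon list in 11Q without knock-in array 1 (-0.043, from -0.043 to 0.52).

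Of 3029 values of named genes and called lists under all settings, called genes kept direction and call in 683 and lost the call in 535, and called lists kept both in 359 and lost the call in 48. Of 67 called genes, 36 lost their call with the RNA quality covariate, 30 with the sex-linked covariate, 29 with the block and 66 with the arrays of the comparison alone, 0 with array weights and 1 with renewed quantile normalisation. Replicate numbers gave no pairing: the mutant array's profile correlated best with the wild type of its own number in 2 of 9 cases. Signal near background limits dim genes, and 3 arrays per group limit all.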

Other observations

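The gene families below, their matched lists, the gene order around Cacna1a and its 3 tests were chosen after the results were seen.

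Genes of the cytosolic ribosome were higher in the 118Q knock-in as a family, with 8 of 49 rising, 47 positive and a median of 0.30 (camera adjusted p = 1.1e-18 over the 9 families; adjusted p = 0.0594 with an estimated correlation). Rps18 rose by 0.63 (SE 0.10), Rps27 by 0.61 (SE 0.10), Rpl41 by 0.55 (SE 0.12) and Rps19 by 0.53 (SE 0.11). Of 76 mitochondrial ribosomal protein genes 3 rose, Mrpl14, Mrps18c and Mrpl57, with a median of 0.19 (camera adjusted p = 8.7e-10; adjusted p = 0.191 with an estimated correlation). Host genes of small nucleolar RNAs, which guide the modification of ribosomal RNA, had 4 of 14 higher, Snhg10, Snhg3, Snhg8 and Snhg7 with 0.56, 0.53, 0.51 and 0.41 (camera adjusted p = 3.9e-05; adjusted p = 0.0594 with an estimated correlation). Of 19 hnRNP genes 0 passed and 14 were negative, with a median of -0.25, and of 35 protocadherin genes 0 passed and 27 were negative, with a median of -0.18 (camera adjusted p = 3.5e-06 and 6.6e-06; adjusted p = 0.0594 for both with an estimated correlation). The 118Q arrays also differed in RNA quality (0.45 against 0.55), and over all genes the 118Q change ran against gene length (Spearman rho = -0.243). With the RNA quality covariate the 5 medians were 0.28, 0.15, 0.44, -0.20 and -0.23. Random lists matched on gene length and level had a median of 0.14 for the cytosolic ribosome (95% of them 0.076 to 0.21) and 0.15 for the mitochondrial family (0.094 to 0.20), a range that holds its 0.19.

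In the Ctm knockout 14 of 94 splicing factor genes rose, among them Rbm25 by 1.17 (SE 0.19), Luc7l3 by 1.19 (SE 0.23) and the kinase gene Clk1 by 1.26 (SE 0.24), although the family's median was 0.0040 (camera adjusted p = 1.5e-05; adjusted p = 0.143 with an estimated correlation). Of 336 genes with Zfp symbols 17 rose, with a median of -0.021 and camera upward (adjusted p = 0.000128; adjusted p = 0.271 with an estimated correlation), as it was in 118Q (adjusted p = 0.0167; adjusted p = 0.423 with an estimated correlation). Small nucleolar RNA host genes were upward by camera in Ctm too, with 2 of 14 rising and a median of 0.0029 (adjusted p = 0.0362; adjusted p = 0.323 with an estimated correlation). Cytosolic and mitochondrial ribosomal protein genes had medians of -0.15 and -0.22, with 44 of 49 and 69 of 76 negative and 0 and 1 falling (camera adjusted p = 0.000128 and 2.1e-12; adjusted p = 0.343 and 0.271 with an estimated correlation). Relative to the wild types of the knock-in lines, Ctm wild types had a median of -0.11 for both splicing factor and Zfp genes. The members that rose belong to the 152 genes higher in the Ctm knockout. On the same scale these 152 had a median of -1.03 in Ctm wild types and -0.096 in Ctm knockouts. Of 174 other probe sets of the genes higher in the Ctm knockout, with a mean of at least 4, 173 also had a positive change.

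Genes near Cacna1a were frequent among the smallest p values of the 11Q line. Of 23 genes with a p below 0.001, 11 lay within 200 measured genes of Cacna1a on chromosome 8, where 0.506 would be expected, so positions by chance are argued against (Fisher's exact test p = 5.4e-13, adjusted 4.9e-12 over 9 such tests). A local effect of the engineered site on adjacent genes is argued against for the set, as 1 of the 11, Gadd45gip1, lay within 20 genes and 10 lay beyond. DNA of a donor strain kept around the altered gene may account for the set of 11 and stays open, since no strain variants or probe sequences were examined. In the Ctm line 5 of 17 falls lay in the same window, 3 of them within 20 genes (Fisher's exact test p = 2.5e-05, adjusted 0.000112), but of the 254 Ctm genes with a p below 0.001, 8 did where 5.58 would be expected (p = 0.277), and of the 152 rises 0 (p = 0.0846), and in the 118Q line 5 of 328 genes with a p below 0.001 (Fisher's exact test p = 0.566).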
